A study of Caenorhabditis elegans with 6 samples.

How the data were processed

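Embryos of wild type N2 and of yap-1(ys38) were collected by bleaching egg-bearing adults, and total RNA of 3 biological replicates per strain was hybridised to 1-colour Affymetrix C. elegans arrays, per the series' design text. The deposited values are MAS5 signals, a probe set intensity on a linear scale, which the authors scaled globally per array, per the design text and the submitters' processing notes. All values were positive, and the mean after trimming 2% at each end was 500.1 in every array. Global scaling equalises total signal, so a change in total RNA per embryo cannot be seen. The authors filtered by detection call, and these calls were not used here. Versions of the signal software beyond its name are not given in the sources used here.

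The 77 control probe sets were left out of tests. Of the other 22548, 13529 with a mean log2 intensity over the 6 arrays above the 40th percentile (a geometric mean of 53.5) were tested. The values were already scaled, so they were only log2-transformed. The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) on wild type replicates 1 and 3 and yap-1(ys38) replicates 1, 2 and 3, the arrays the study kept. Intervals are 95%. The median standard error of a log2 fold change was 0.27. Comparisons, gene lists, alternatives and the rule for named genes were set before the data were examined, except where a later choice is stated.

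Probe sets were named through the platform annotation: 20766 had 1 gene symbol, 887 several and 895 none listed, and 20701 single symbols matched the RefSeq table of assembly WBcel235, which changed 0 symbols. Genes were named only from probe sets with 1 symbol, and a gene with several probe sets was represented by the brightest of those tested, which left 10237 genes. Named genes were yap-1 and the Hippo list, then up to 12 genes per direction with the largest change among those passing the adjusted test with no overlap between strains, places left over going to unadjusted p under 0.01 with no overlap (6 higher and 2 lower, all from this second part), then up to 4 genes per list with the lowest p.

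The 22 lists held 740 genes, of which 711 were measured and 583 tested. They cover the Hippo pathway, polarity and junctions, trafficking, actomyosin, intestinal lumen and identity, muscle, neurons, epidermis, collagens, hedgehog-related genes, maternal and zygotic genes, cell cycle, histones, ribosomal proteins, heat shock, detoxification, immunity and lipid metabolism, with yolk and sperm lists for carried-over adult material. They were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), and with an estimated correlation and fry as alternatives. Likeness was the Pearson correlation of log2 values, and RNA quality the mean log2 ratio of 3-prime to 5-prime signal of 4 control transcripts (GAPDH, actin, ubiquitin and catalase): 2.68, 3.64 and 3.74 in wild type replicates 1, 2 and 3 and 2.86, 3.00 and 3.07 in the yap-1(ys38) arrays.

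The replicate numbers come from the sample titles, which do not say what they mark. Deviations of same-numbered arrays from their strain means correlated at 0.364, 0.345 and 0.445 for numbers 1, 2 and 3, and those of differently numbered arrays at 0.015 or less, so the numbers were taken to pair the arrays, and a fit with the number as a block was run beside the unblocked one. With the arrays compared, only numbers 1 and 3 are shared and 1 residual degree of freedom remains. The test was tried on simulated data of 13529 probe sets with the arrays and spreads of this comparison: of 50 probe sets changed at each size, 17 were called at 2-fold (34%), 43 at 4-fold (86%), 49 at 8-fold (98%) and 48 at 16-fold (96%), with 10 false calls. All sizes were planted together, which eases the adjustment, so these rates and those below do not hold for 1 change standing alone. With the block the test made 58 false calls, and 44 where nothing was changed. These arrays were simulated as independent, and where nothing was changed gave 673 probe sets at an unadjusted p under 0.05, against 141 in the data. With same-numbered arrays correlated at 0.385, the mean found here, 14, 47, 49 and 50 of 50 were called, with 3 false calls, and unchanged data gave 255 probe sets at an unadjusted p under 0.05 and 1 call with the block. Alternatives covered the arrays in the fit, the block, quantile normalization and median centring, the filter, a floor, the variance model, the methods' t-test and leaving out each replicate.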

Results

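Messenger RNA of Caenorhabditis elegans embryos was measured on Affymetrix C. elegans arrays in the wild-type strain N2 and in the mutant strain yap-1(ys38), with 3 biological replicates of each strain and 1 array per replicate. yap-1 encodes the worm counterpart of YAP, the transcriptional coactivator that the Hippo kinase cascade restrains. The comparison was made to look for genes through which this pathway keeps cells polarised. Each array carried 22625 probe sets, of which 13529 were bright enough to be tested. The median intensity was 123 and 123 (wild type replicates 1 and 3), 86.6 (wild type replicate 2) and 124, 118 and 133 (yap-1(ys38) replicates 1, 2 and 3), and the number of arrays limits the precision. The study set wild type replicate 2 aside as unlike the other wild-type arrays, so the comparison of strains rests on wild type replicates 1 and 3 against the 3 yap-1(ys38) arrays. Values of replicate 2 are given beside it.

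The mutated gene came first. The single yap-1 probe set read 267 and 555 in wild type replicates 1 and 3 and 371, 260.4 and 302 in yap-1(ys38) replicates 1, 2 and 3. On the log2 scale the means were 8.59 ± 0.75 (SD, n = 2) in wild type and 8.27 ± 0.26 (SD, n = 3) in the mutant. The log2 fold change was -0.32 with a 95% confidence interval from -1.10 to 0.45 (limma, adjusted p = 1), so the strains did not differ beyond the spread between replicates. The wild-type replicates differed more from each other than the strain means did, and without wild type replicate 3 the log2 fold change was 0.20. Wild type replicate 2 read 443. The labels do not state which part of the gene the allele changes, and where this probe set lies relative to it is not known, so its level does not check the genotype.

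The largest difference between the strains among the genes chosen by rule belonged to ND5, the mitochondrially encoded subunit of respiratory complex I. Its probe set read 73.1 and 46.6 in wild type replicates 1 and 3 against 432, 237 and 406 in the 3 yap-1(ys38) arrays (log2 fold change 2.57, SE 0.37), with 61.4 in wild type replicate 2. These wild-type values lie near the filter intensity of 53.5 and detection calls were not used, so the size of the change is uncertain. The other 7 mitochondrially encoded genes tested had log2 fold changes from -0.18 to -0.01. They read 2032 to 22081 over the 6 arrays, far above ND5, so the signals compared are unlike in level. ark-1, a tyrosine kinase of the Ack family that dampens EGF receptor signalling, read 1276 and 1400 in wild type against 2277, 2027 and 1895 (log2 fold change 0.62, SE 0.18) at its brighter probe set, while the other gave 0.02. At their brightest probe set, 4 other genes had all yap-1(ys38) arrays above wild type replicates 1 and 3 and an unadjusted p under 0.01. They were folt-3 of the folate transporter family (log2 fold change 2.02, SE 0.58), nspe-7 (1.93, SE 0.59), gyf-1 (1.49, SE 0.39) and ZC190.4 (1.37, SE 0.35). folt-3, gyf-1 and ZC190.4 read at most 57.5 in wild type replicates 1 and 3, so the size of their changes is uncertain too. The same holds for nspe-7, at 63.9 in wild type replicate 3. Without wild type replicate 1 the log2 fold change of folt-3 was 1.19 and without wild type replicate 3 it was 2.86, and for nspe-7 these were 2.64 and 1.22. Below wild type by the same rule lay aex-5, a proprotein convertase, at 152 and 185 against 44.9, 45.5 and 76.2 (log2 fold change -1.64, SE 0.39, its size uncertain as some values lie under 53.5), and ost-1, the worm SPARC protein of basement membranes, at 9102 and 12990 against 7847, 6037 and 6205 (-0.71, SE 0.19), its other probe set giving -0.12, with -0.97 without wild type replicate 1 and -0.45 without wild type replicate 3. In wild type replicate 2 the 6 higher genes also read below every yap-1(ys38) array, whereas aex-5 at 18.2 and ost-1 at 3561 read below every yap-1(ys38) array too, opposite to the other wild-type arrays.

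None of these 8 genes passed the adjusted test. Across all 13529 probe sets limma called 0 at an adjusted p under 0.05 (lowest adjusted p 0.941, that of ND5), and 141 had an unadjusted p under 0.05, 89 higher and 52 lower in yap-1(ys38), where 676 would be expected by chance if the arrays were independent. The methods' t-test at their threshold called 202 probe sets, 121 higher and 81 lower. With at least a 2-fold change it called 13, 11 higher and 2 lower, and after Benjamini-Hochberg adjustment 0. The yap-1(ys38) arrays all lay on 1 side of both wild-type arrays at 1464 probe sets (10.8%), against 20% by chance under the same assumption. Same-numbered arrays of the strains deviated together, which lowers such counts. With all 6 arrays the strains gave 115 probe sets at an unadjusted p under 0.05. The other splits of the arrays that part all 3 same-numbered pairs gave 60, 143 and 194, too few splits for a test. With the replicate number as a block limma called 12 probe sets, 11 higher and 1 lower, 8 of them with 1 gene symbol: ND5 (adjusted p = 2.05e-06), nspe-7, tts-1, clec-174, C50F7.5, F47G4.4, clx-1 and, lower, bcf-1, of which all but ND5 and nspe-7 were chosen after their values were seen. Over its alternatives the adjusted p of ND5 ran from 2.05e-06 to 1. Unchanged simulated data gave 44 calls under the same block with independent arrays and 1 with arrays paired at the mean correlation of these. Without the block the paired simulation gave 255 probe sets at an unadjusted p under 0.05, against 141 here. It thus does not match these arrays, and the 12 calls cannot be judged by it. With all 6 arrays, which hold all 3 pairs, the block called 0 (lowest adjusted p 0.93), and 329 probe sets had an unadjusted p under 0.05. Without wild type replicate 1 limma called 3 probe sets: clec-174 and gfi-1 higher and bcf-1 lower. The bcf-1 probe set read 46.8, 1229 and 5528 in wild type replicates 1, 2 and 3 and 18.6, 50.1 and 41.9 in the yap-1(ys38) arrays of the same numbers. Arrays numbered 1 moved little at nspe-7 (171 and 214 in wild type and yap-1(ys38)), tts-1 (1270 and 1386) and clx-1 (157.5 and 172). The same held for C50F7.5 (239 and 251), and clec-174 read lower (7989 and 7178). Arrays numbered 3 carried these rises, as at clx-1 (73.9 and 983). F47G4.4 rose in both pairs (114 and 239, 96.7 and 352), at a probe set not its brightest. The 4 called probe sets with several symbols or none read lower in yap-1(ys38) 2 than in wild type 2.

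**Figure D1:**
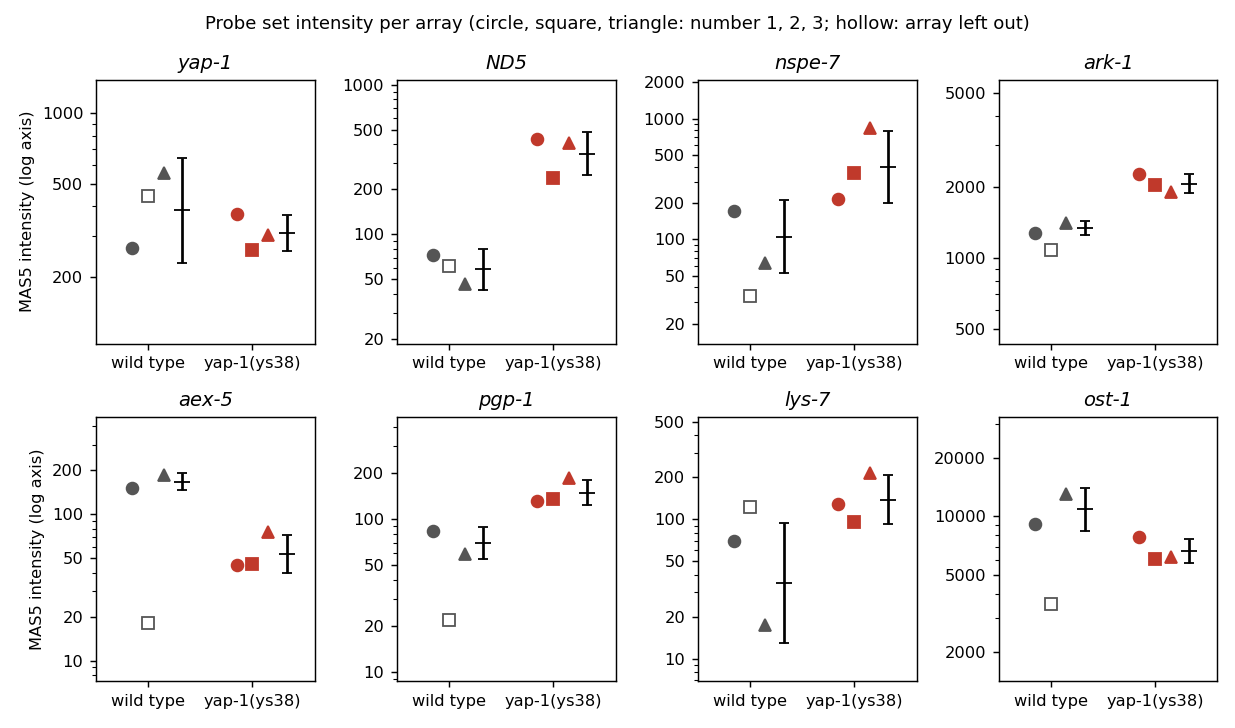
MAS5 intensity (vertical log axis, arbitrary units) of yap-1, ND5, nspe-7, ark-1, aex-5, pgp-1, lys-7 and ost-1 in each array, by strain; circles, squares and triangles mark replicate numbers 1, 2 and 3, and the hollow square is wild type replicate 2, left out of the comparison. Horizontal ticks with bars are the mean and SD of the log2 values of the arrays compared; ND5 lies at 46.6 to 73.1 in the 3 wild-type arrays and at 237 to 432 in the yap-1(ys38) arrays.

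None of the genes closest to the question passed the test between strains. Of the Hippo list, 10 of 11 members were measured and tested, and 0 rose or fell, over all genes tested or adjusted over the list alone (median log2 fold change -0.08, camera adjusted p = 0.423). wts-1, the Warts kinase, had a log2 fold change of -0.09 (SE 0.18), cst-1, the Hippo kinase, 0.02 (SE 0.18), sav-1 -0.15 (SE 0.21), mob-1 0.04 (SE 0.19) and nfm-1, the merlin counterpart, -0.18 (SE 0.41). The 14-3-3 genes ftt-2 and par-5 stood at -0.06 (SE 0.15; up to 0.11 at its other probe sets) and 0.08 (SE 0.13). egl-44, the worm TEAD factor through which YAP acts on DNA, gave -0.24 (SE 0.21) at its brighter probe set and 0.63 at the other, and its partner egl-46 gave 0.17 (SE 0.26). Of the 30 cell polarity and junction genes tested, 19 lay higher and 11 lower, none past the threshold (median 0.05, adjusted p = 0.541), with par-3 at 0.22 (SE 0.20) and crb-1 Crumbs at -0.32 (SE 0.29). Probe sets of the same gene disagreed for unc-44 ankyrin (4 higher and 4 lower, from -0.31 to 0.26) and vab-10 (3 higher and 1 lower, from -0.29 to 0.32). The 27 polarised trafficking genes had a median of -0.01 and a mean of 0.03 (adjusted p = 0.956), with rab-35 at 0.79 (SE 0.32) and arf-6 at -0.33 (SE 0.27), and the 14 actomyosin genes a median of 0.05 (adjusted p = 0.405), with ced-10 Rac at 0.25 (SE 0.22) and mlc-4 at -0.10 (SE 0.15).

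Of the 22 gene lists, 4 shifted in camera with its preset correlation, all toward lower values in yap-1(ys38), while none of their members passed the test over all genes or adjusted over the list alone. Of the 25 body wall and pharyngeal muscle genes, 20 lay lower (median log2 fold change -0.18, adjusted p = 0.00125), among them act-4 actin (-0.27, SE 0.15), the troponin genes tnc-2 (-0.33, SE 0.25) and tni-1 (-0.30, SE 0.24) and deb-1 vinculin (-0.23, SE 0.18, against 0.28 at its other probe set). Of the 15 intestinal lumen and brush border genes, 12 lay lower (median -0.26, adjusted p = 0.00995), with the intermediate filament genes ifc-2 (-0.64, SE 0.37) and ifd-1 (-0.50, SE 0.32) and the aquaporin aqp-4 (-0.43, SE 0.27). pgp-1, a P-glycoprotein transporter of the same list, stood the other way, at 83.3 and 59 in wild type against 131, 137 and 187 (log2 fold change 1.10, SE 0.35, adjusted p = 0.188 over the list alone). Of the 74 cytosolic ribosomal protein genes, 65 lay lower by a small amount (median -0.08, adjusted p = 3.23e-06), as rpl-28 (-0.29, SE 0.13) and rpl-3 (-0.21, SE 0.12) did. Of the 52 hedgehog-related and patched-related genes, 38 lay lower (median -0.11, adjusted p = 0.0335), with grl-7 (-0.35, SE 0.20) and wrt-1 (-0.26, SE 0.15) lower and wrt-10 (0.28, SE 0.17) and grl-25 (0.51, SE 0.33) higher. None of the 4 held with an estimated correlation (adjusted p = 0.817 for each).

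Leaving out 1 array ended these 4 calls in 2 cases each. Without wild type replicate 3 the adjusted p was 0.322 for muscle (median 0.05), 0.71 for the lumen, 0.1 for ribosomal proteins and 0.836 for the hedgehog-related list. Without yap-1(ys38) replicate 2 it was 0.126, 0.0706, 0.0706 and 0.404. Wild type replicate 3 also had the highest 3-prime to 5-prime signal ratio of the control transcripts, 6.28 for GAPDH against 2.08 in wild type replicate 1 and 2.78 to 3.06 in the yap-1(ys38) arrays. With all 6 arrays the medians turned to 0.41 for muscle (adjusted p = 0.00099), 0.25 for the lumen (0.0414), 0.33 for the hedgehog-related list (0.00099) and 0.04 for ribosomal proteins (0.283), and with an estimated correlation none of the 4 was called (adjusted p = 0.685, and 0.848 for ribosomal proteins). Quantile normalization kept the direction of all 4 and ended the call for ribosomal proteins (adjusted p = 0.0896). With the replicate number as a block the lumen list stayed lower (adjusted p = 0.0193), muscle (0.0803), ribosomal proteins (0.14) and the hedgehog-related list (0.296) were no longer called, and 3 other lists were: collagens higher (1.26e-06), heat shock genes higher (0.000371) and zygotic cell fate genes lower (0.0193). With the block and an estimated correlation each of these 4 lists had an adjusted p of 0.833. Across alternatives the adjusted p spanned 1.24e-09 to 0.988 for muscle, 1.31e-06 to 0.988 for the lumen, 3.11e-07 to 0.988 for ribosomal proteins and 5.97e-07 to 0.988 for the hedgehog-related list.

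The remaining lists did not shift in camera, and 0 of their members passed over all genes or adjusted over the list alone. Closest to the threshold were the maternal and early embryo genes, 22 of 27 higher (median 0.12, adjusted p = 0.0577), with the P granule gene pgl-1 at 0.77 (SE 0.35) and pos-1 at -0.19 (SE 0.13; 0.045 at its other probe set). They passed after quantile normalization (adjusted p = 0.0371), and with all 6 arrays they stood lower (median -0.17, adjusted p = 0.00913). With an estimated correlation they were not called (0.817, and 0.685 with all 6 arrays). Among collagens, col-63 stood at 0.89 (SE 0.33) and col-177, near 53.5 in yap-1(ys38) and so of uncertain size, at -0.93 (SE 0.40). Collagens as a list had 45 of 76 genes higher (median 0.07, adjusted p = 0.0819). With the preset correlation they were called higher with all 6 arrays (median 0.66, adjusted p = 1.8e-08), without wild type replicate 1 (0.30, 0.00163) and without yap-1(ys38) replicate 2 (0.16, 1.15e-05), while without yap-1(ys38) replicate 3 the median was -0.003 (0.876). With an estimated correlation the first 3 fits gave an adjusted p of 0.685, 0.723 and 0.953. The intestinal cell identity list (median -0.13, adjusted p = 0.0847) and the neuron list (median -0.08, adjusted p = 0.0923) lay lower, with the protease asp-1 at -0.34 (SE 0.26) and the touch receptor channel mec-4 at -0.76 (SE 0.36). Zygotic cell fate genes had a median of -0.12 (adjusted p = 0.147), with the muscle factor hlh-1 at -0.45 (SE 0.28). Innate immunity genes had a median of -0.09 (adjusted p = 0.405), with the lysozyme genes lys-7 higher and lys-4 lower in yap-1(ys38). Some values of both lay under 53.5, and leaving out 1 replicate moved lys-7 from 0.98 to 3.00 and lys-4 from -2.12 to -0.99, so the sizes of these changes are uncertain. Medians were 0.07 for epidermis and cuticle (adjusted p = 0.264), -0.02 for the cell cycle (0.405), 0.04 for histones (0.502), 0.04 for detoxification (0.502), 0.02 for heat shock (0.541) and 0.05 for lipid metabolism (0.786), in which fasn-1, the fatty acid synthase, stood at 0.37 (SE 0.17). Yolk and adult soma genes had a median of 0.05 (adjusted p = 0.558) and sperm genes -0.02, with a mean of 0.07 (0.96), and wide spreads within a strain: the yolk protein gene vit-5 read 2028 and 7.56 in wild type replicates 1 and 3 and 1700, 265 and 21.2 in yap-1(ys38).

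Of these 18 lists, 12 were called under some alternative, collagens and maternal genes included, in 59 of 468 tries, all with the preset correlation. With an estimated correlation none was called, either with all 6 arrays (lowest adjusted p of all 22 lists 0.685) or on leaving out any 1 replicate (0.69). The calls below use the preset one. With all 6 arrays the calls were neurons higher (median 0.44, adjusted p = 0.00248), epidermis higher (0.21, 0.00099), detoxification higher (0.20, 0.0356), cell cycle lower (-0.14, 0.000218), zygotic genes lower (-0.23, 0.00562) and sperm lower (-0.34, 0.00476). Without wild type replicate 1, neurons (-0.38, 4.02e-05) and innate immunity (-0.31, 0.0212) were called lower, and epidermis (0.18, 0.00981), heat shock (0.34, 0.00153), yolk (2.15, 1.75e-05) and sperm (1.25, 4.1e-08) higher. Without wild type replicate 3, heat shock (-0.15, 0.0132), yolk (-2.47, 8.77e-06), sperm (-0.93, 1.82e-12) and intestinal identity (-0.22, 0.0461) were called lower. Without yap-1(ys38) replicate 1, maternal genes were called higher (0.26, 1e-05) and intestinal identity (-0.21, 0.0102) and sperm (-0.33, 0.00685) lower. Without yap-1(ys38) replicate 3, neurons (-0.20, 0.00229) and innate immunity (-0.22, 0.0313) were called lower and epidermis higher (0.16, 0.0109).

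**Figure D2:**
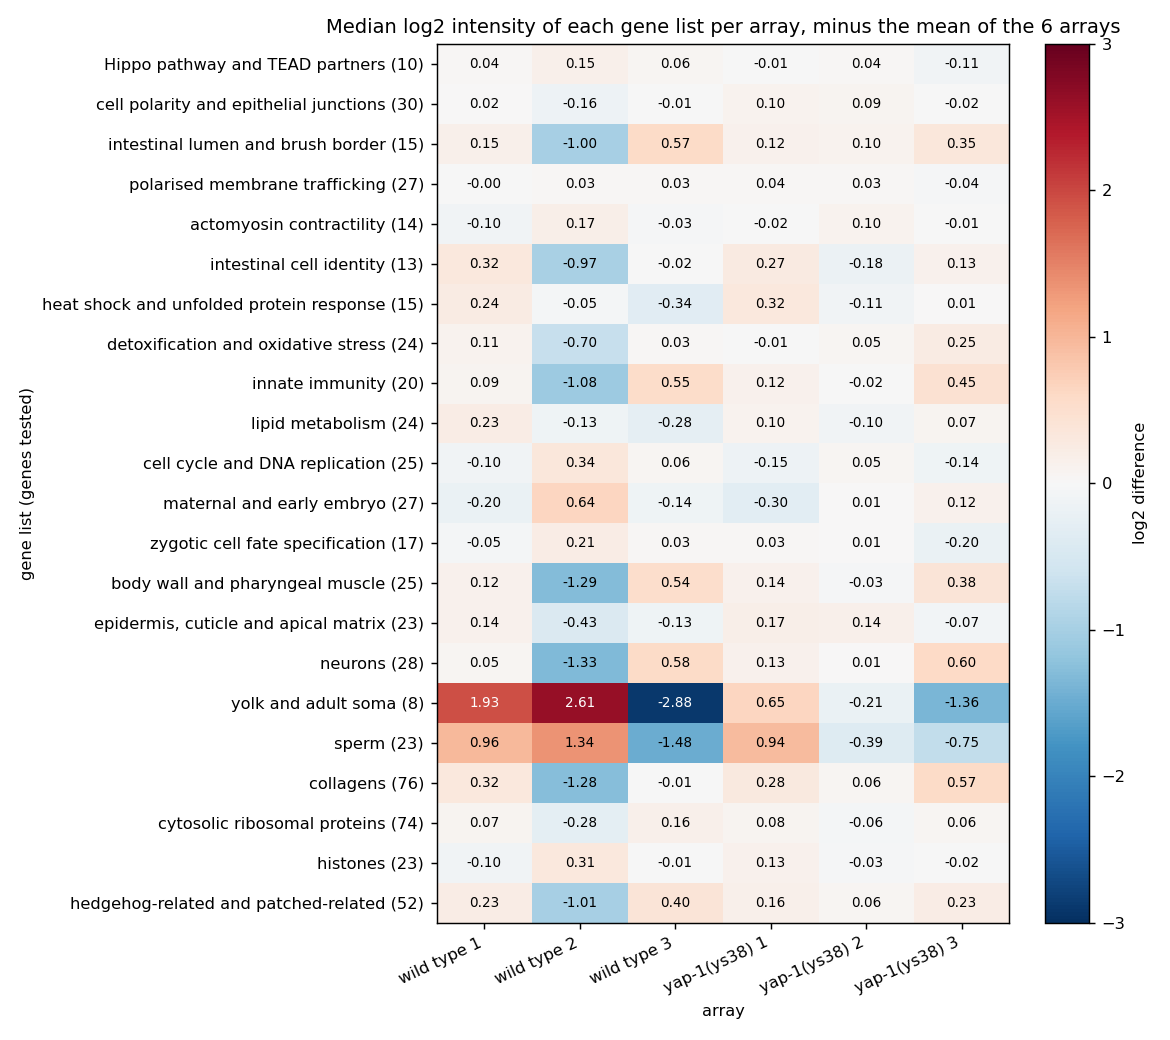
Median log2 intensity of each of the 22 gene lists in each array (columns), minus the mean of the 6 arrays, with the number of genes tested in brackets; red is higher and blue lower. Wild type replicate 2 is lowest of the 6 for muscle (-1.29), neurons (-1.33) and collagens (-1.28) and highest for maternal genes (0.64), while yolk genes run from -2.88 to 2.61.

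Same-numbered arrays of the 2 strains resembled each other closely. Across the probe sets tested, which are not independent replicates, the highest of the 15 correlations was between wild type replicate 1 and yap-1(ys38) replicate 1 (Pearson r = 0.979), followed by wild type replicate 3 with yap-1(ys38) replicate 3 (r = 0.965), whereas wild type replicates 1 and 3 correlated at 0.936. Wild type replicate 2 stood apart, with a mean r of 0.879 to the other 5 arrays against 0.930 to 0.951 for the rest, and its best partner was yap-1(ys38) replicate 2 (r = 0.908). Against the mean of wild type replicates 1 and 3 it gave lower signals for muscle, nerve and gut genes. All 25 muscle genes lay below both, with a median log2 difference of -1.67, for example myo-1 myosin (512 against 1946 and 3509 in replicates 1 and 3). Of 28 neuronal genes, 26 lay below both (median -1.62), as cha-1, the acetylcholine synthesis enzyme, did at 17.4 against 206 and 252. The brush border median was -1.34, with act-5, the microvillar actin, at 1054 against 3498 and 4452. These differences carry no test, since they describe 1 array.

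**Figure D3:**
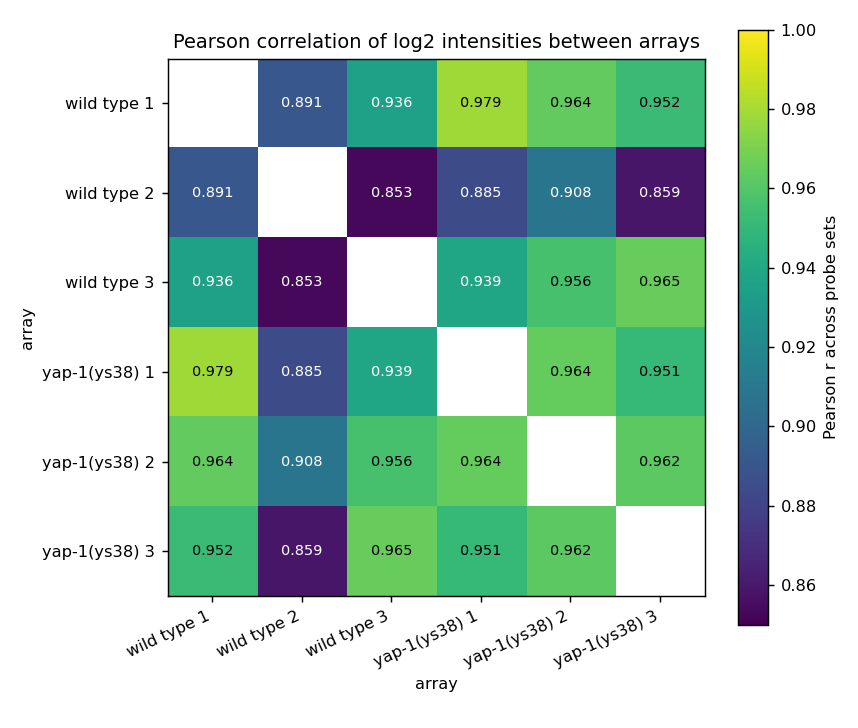
Pearson correlation of log2 intensities across the tested probe sets for each pair of the 6 arrays (both axes list the arrays; colour and number give r). The row of wild type replicate 2 is the darkest, at 0.853 to 0.908, and the brightest cell joins the 2 arrays numbered 1, at 0.979.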

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

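The tests of RNA quality and embryo age here were chosen after the values had been seen. Wild type replicate 2, which the comparison of strains does not use, held 6 gene lists above both other wild-type arrays by more than those differed from each other. Its list medians exceeded the mean of wild type replicates 1 and 3 by 0.85 on the log2 scale for maternal and early embryo genes (26 of 27 above both, such as the eggshell gene perm-2 and the yolk receptor gene rme-2, at 890 against 396 and 191 in replicates 1 and 3), 0.48 for histones (17 of 23 above both), 0.43 for cell cycle and DNA replication (19 of 25 above both, such as mcm-6 and air-1), 0.37 for zygotic cell fate genes (8 of 17 above both and 4 below both, end-1 and tbx-38 among the higher), 0.25 for actomyosin contractility (9 of 14 above both) and 0.15 for the Hippo list (5 of 10 above both and 2 below both). Groups of 3 arrays are too small for a test of single outlying values, and none was made.

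The following was weighed for the distance of this array. RNA degradation alone is argued against by replicate 3. Wild type replicates 2 and 3 had the highest 3-prime to 5-prime ratios of the 6 arrays for each of 4 control transcripts, yet their correlation with each other, 0.853, was the lowest of the 15 pairs. Of these ratios, GAPDH (6.28 against 4.39) and actin (10.4 against 9.04) were higher in replicate 3, and catalase (22.1 against 17.5) and ubiquitin (27.9 against 27.7) in replicate 2. Array scaling is argued against by the muscle genes, whose median difference from replicates 1 and 3 was -1.63 after quantile normalization and -1.67 before. Younger embryos in that collection stay open and untested. Of 9 lists that mark early and late embryos, 9 lay on the side this needs and beyond all 5 other arrays, but these lists were picked after their values were seen, so they restate the pattern. Yolk and sperm genes, which mark adult material, were also high in this array, but wild type replicate 1 and yap-1(ys38) replicate 1 shared that without low muscle genes, and embryo ages are not stated in the labels. In the maternal list perm-2 varied like the yolk genes, at 214, 813 and 13.8 in wild type replicates 1, 2 and 3. Other genes of that list with large departures in replicate 2 had the same order. These were perm-4 (550, 828 and 127), rme-2 (396, 890 and 191) and egg-1 (277, 521 and 156). The median of that list against the mean of the 6 arrays did not vary like the yolk genes, at -0.201, 0.635 and -0.138.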

How the results depend on the processing

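For the genes changed, 17 of 21 alternatives also gave 0 calls. The replicate block gave 12, the methods' t-test at their threshold 202 and with a 2-fold change 13, and leaving out 1 replicate 0 to 3. The block, with 1 residual degree of freedom, made 44 calls in unchanged simulated data with independent arrays and 1 with paired arrays, and with all 6 arrays it made 0. Neither simulation matched the data in probe sets at an unadjusted p under 0.05 without the block (673 and 255 against 141). A lone wild-type array left by an omission is assumed to vary like the others. The yap-1 log2 fold change stayed uncalled in all 18 alternatives, from -0.85 to 0.20, and the correlation of wild type replicate 2 with the other arrays was 0.881 without the filter and 0.890 as Spearman's. Of 100 other named genes, 2 were called under any alternative, ND5 and nspe-7 with the block, and 49 changed sign in at least 1. Leaving out 1 replicate moved 86 of them over 1.5 times or across 0. The block changed no call other than those given with the results. Scaling moved the median of all probe sets by -0.004 (quantile) and -0.01 (median centring).

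The list shifts depended on the arrays. Adjusted p-values for muscle, lumen, hedgehog-related and ribosomal lists, in that order, were as follows. With all 6 arrays muscle, lumen and hedgehog-related turned higher, at 0.00099, 0.0414 and 0.00099, and with the block as well at 6.64e-05, 0.0201 and 0.000144. Ribosomal was not called in either fit (0.283 and 0.256). The block with an estimated correlation gave 0.833 for each, and the block alone ended 3 calls (muscle 0.0803, hedgehog-related 0.296, ribosomal 0.14). With wild type replicates 1 and 2, all turned higher, at 1.24e-09, 0.000379, 5.97e-07 and 0.000514. With all 6 arrays and the 3-prime to 5-prime ratio as covariate, muscle stayed called higher (0.0257). Lumen (0.339) and hedgehog-related (0.0969) lay higher but were no longer called, and ribosomal was not called (0.71). With all 6 arrays and array quality weights, 0.219 for wild type replicate 2, muscle (0.889), lumen (0.617) and hedgehog-related (0.943) were not called, with medians of 0.003, -0.104 and 0.028, and ribosomal stayed lower (0.00422). An estimated correlation gave 0.817 for each, with all 6 arrays 0.685 (ribosomal 0.848), 0.723 without wild type replicate 1, 0.89 without wild type replicate 3, 0.875 without yap-1(ys38) replicate 1 or 3, and 0.953 (lumen, ribosomal) or 0.959 (muscle, hedgehog-related) without yap-1(ys38) replicate 2. Fry gave 0.964 in 1 direction and 0.988 in either direction for each. Quantile normalization ended ribosomal (0.0896) and no filter hedgehog-related (0.0839). Leaving out 1 replicate gave 4.1e-08 to 0.322, 0.000941 to 0.71, 0.00229 to 0.836 and 3.11e-07 to 0.1.

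Of the 18 lists not called, 12 were called under some alternative, in 59 of 468 tries, none with an estimated correlation. Those that turned were neurons higher (all 6 arrays 0.00248, with the block 0.000241, wild type 1 and 2 6.05e-08, all 6 with the covariate 0.0182), maternal genes lower (0.00913, 0.00518 and, wild type 1 and 2, 0.000216), innate immunity higher (all 6 with the block 0.0202, wild type 1 and 2 0.000379) and yolk lower (all 6 with the block 0.0252, wild type 1 and 2 7.42e-05, all 6 with the covariate 0.0182). Leaving out 1 replicate turned yolk (8.77e-06 to 0.769), sperm (1.82e-12 to 0.656) and heat shock (0.00153 to 0.418). Chosen after seeing the data were wild type replicates 1 and 2 and the covariate, for lists and single genes (yap-1 included) also array weights, stricter filter, floor and all 6 with the block, for lists median centring and estimated correlations other than with the arrays compared and no block, and for single genes no filter and the robust trend. Causes were not tested. Probe sets near the filter intensity of 53.5 have the least signal over background.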

Other observations

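Of the tests below, the covariate fit for ND5 and the count of splits by unadjusted p were set before their results were seen, and the others after. Genes of adult and stress origin varied widely between arrays of 1 strain. The yolk protein genes vit-4 and vit-6 read 2221 and 2083 in wild type replicate 1, 4583 and 2393 in replicate 2 and 40.3 and 68.3 in replicate 3, and in yap-1(ys38) replicates 1, 2 and 3 vit-4 read 1468, 261 and 77.2. The major sperm protein gene msp-152 read 182, 174 and 3.33 in wild type replicates 1, 2 and 3 and 223, 73 and 69.5 in yap-1(ys38). The small heat shock gene hsp-16.41 read 2028, 535 and 27.1 in wild type and 1999, 39.2 and 130 in yap-1(ys38), each in order of replicate number. Within the pair of arrays numbered 3, 18 of 25 muscle genes lay lower in yap-1(ys38) (median -0.18), within the pair numbered 1, 11 of 25 (median 0.01), and within the pair numbered 2, 1 of 25 (median 1.41). For collagens the same medians were 0.40, -0.07 and 1.37, and for the cell cycle list -0.22, -0.04 and -0.32. Hippo and polarised trafficking medians were also below 0 in each pair, and epidermis and heat shock medians above 0 in each.

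Same-numbered arrays of the strains deviated together. A shared difference in RNA degradation as the whole cause is argued against only weakly by numbers 2 and 3. These had close mean 3-prime to 5-prime ratios in both strains, above that of number 1. Across strains their deviations correlated at -0.308 (wild type 2 with yap-1(ys38) 3) and -0.169 (wild type 3 with yap-1(ys38) 2), where this cause needs positive values. Deviations from a mean of 3 arrays sum to 0, however, which lowers the correlations of differently numbered arrays. The yap-1(ys38) ratios also span only 2.86 to 3.07. Shared embryo age or carried-over adult material stays open. The order of arrays was the same in both strains in 4 of 10 tissue, adult and stress lists. This cause needs like orders and the other lists differed, but no deciding count was set, so the count decides nothing. No label states the age of a collection. The labels do not name a shared day either.

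Of the 10 splits of the 6 arrays into 3 and 3, 10 gave as many calls past the adjusted threshold as the real one, which decides nothing, since the real one gave 0 and no split can give fewer. The highest of the others was 0. At unadjusted p under 0.05 the real split gave 115 probe sets and the highest of the others 894, and 9 splits, the real one included, gave at least as many as the real one. That number of splits is too small for a share under 0.05. The split with 894 set wild type replicates 1 and 2 and yap-1(ys38) replicate 1 against the rest, which points to a structure of the samples. The 4 splits that part all 3 pairs, the real one among them, gave 60 to 194, and the 6 that part 1 pair gave 535 to 894.

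ND5 read higher in every yap-1(ys38) array than in every wild-type array, the latter near the filter intensity of 53.5. A general rise of mitochondrial RNA is argued against by the other 7 mitochondrial genes, with a median log2 fold change of -0.066, though these read far brighter than ND5. RNA degradation in wild type is argued against by the fit of all 6 arrays with the 3-prime to 5-prime ratio as a covariate, in which the change was 2.36 (SE 0.42, adjusted p = 1, as before past no adjusted threshold). A difference between the strains in mitochondrial DNA sequence under the probes cannot be told apart from a difference in ND5 RNA, since 1 probe set covers the gene and its probe sequences were not used here. Chance stays open too, since ND5 had the lowest adjusted p of 13529 probe sets in the main limma fit, and that was 0.941.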
